A study of Xenopus tropicalis with 27 samples.

How the data were processed

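RNA from Xenopus tropicalis tadpole brains was sequenced in 27 libraries. Per the labels, each group had 3 libraries and each drug or DMSO library pooled 3 brains taken at stage 46, after exposure from stage 30 on. The drug groups were 10 µM β-estradiol, 5 µM cyclopamine and DMSO, and the untreated groups were stages 40, 42, 44, 45, 46 and 47. Groups were taken from the labels alone. Labels gave replicate numbers, but nothing there tied equal numbers to a shared clutch or day, so p-values measured the spread between these samples, which may in part be technical.

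The authors deposited whole-number read counts per gene in a drug table (9 libraries) and a time course table (18 libraries). The submitters' processing notes list STAR 2.7.3. The genome build, the annotation, the read counter and its use of strand are not given in the sources used here. From the values, each deposited row reached 1 CPM in at least 3 libraries of its table, so the tables had been filtered. The authors also deposited normalized values, which from the values themselves were log2(CPM + 1) after full-quantile normalization: turned back to CPM, each library of the drug table summed to between 998443 and 998449. Genes were named by the symbols in the files, and list members also through the synonyms of the gene table given with the data. No coordinates were used. No usable symbol was given for 3183 of 16212 genes of the drug table (19.6%) and for 3135 of 16049 genes of the time course (19.5%). These genes were tested and counted but not named. Members of gene families with near-identical copies, such as globins, keratins and the tandem copies whose symbols end in a point and a digit, may share reads and are uncertain as single genes.

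Total counts ran from 17.6 to 28.5 M per drug library and from 12.9 to 48.3 M per time course library. A floor of 3 counts corresponded to between 0.105 and 0.17 CPM in a drug library. Where a group had 0 counts, the fold was bounded against 3 counts over that group's libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

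Each table was fitted separately in edgeR 4.0.16 under R 4.3.3, on the deposited counts, with TMM factors, filterByExpr (which removed 0 genes in each table), group means without covariates, and the robust quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are given as log2 values ± SE with 3 libraries per group, and levels as CPM ± SD. Contrasts were each drug against DMSO, the drugs against each other, stage 47 against stage 40, each pair of adjacent stages, and any difference among the 6 stages. The report tests no level across the 2 tables, which were normalized separately; 2 early tests of an explanation did so and are named where that explanation is weighed.

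Before the data were examined, 41 gene lists (pathways, cell types, brain regions, and tissues that a dissected brain may carry along) were fixed, together with the rule for named genes and the alternatives. A list with at least 3 measured members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. That test was repeated with an estimated correlation and with fry, whose p asks whether a list's genes move on balance one way. Stage-rising and stage-falling lists held the 200 genes with the lowest p among those at least 1 log2 unit higher or lower at stage 47 than at stage 40. The named genes were, per main contrast, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, with all 3 libraries of a group beyond all 3 of the other, and a symbol that was not a placeholder. For the drugs against each other the number was 5 each way, and for adjacent stages 2 each way. Each list could add up to 4 called members with the lowest p, and Hedgehog, estrogen and autism genes were reported whatever their values. Of these, the text gives the ones that describe each group; a gene outside this rule is said to be so. Some genes that the rule names are not reported here.

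The drug comparisons share the DMSO libraries. For the overlap and correlation of the 2 drugs, all 9 libraries of the drug table were therefore simulated 20 times as unchanged. The simulated DMSO libraries, like the others, were drawn around the real DMSO means. Tests were checked on simulated data in which 200 genes changed. For estradiol against DMSO, with 16211 genes, edgeR recovered 7.46% of 1.5-fold, 59.7% of 2-fold and 81.8% of 4-fold changes, and 6.6% of its calls were false. For stage 47 against stage 40, with 16045 genes, it recovered 67.2%, 83.6% and 97% of the same folds, with 6.78% false. DESeq2 gave 22.3% false calls in the first simulation and 11.2% in the second. All groups were simulated with the same spread per gene, whereas real DMSO libraries varied less than estradiol libraries (biological coefficient of variation 0.0899 against 0.227). These rates may therefore not carry over to the drug comparisons.

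Alternatives were relative log expression size factors, other filters, DESeq2 1.42.0, limma on the deposited log2 values, fits of only the groups compared, the replicate number as a block, and leaving out each library. A filter at 5 CPM in at least 3 libraries, a fit with cyclopamine replicate 1 alone in its group (assumed to vary like the other groups), and a lysosome list were added after the data had been seen. Replicates differed by more than sampling noise in each group, with a lowest chi-square per degree of freedom of 2.66.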

Results

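The data were read counts from stage 46 tadpole brains raised from stage 30 in β-estradiol (an estrogen), in cyclopamine (a plant alkaloid that blocks Smoothened, the signal transducer of the Hedgehog pathway) or in the solvent DMSO, and from untreated brains at 6 stages. Each of the 9 groups had 3 libraries. Depth was 17.6 to 28.5 M counts in the drug libraries and 12.9 to 48.3 M in the untreated ones. The biological coefficient of variation was 0.227 between estradiol libraries, 0.21 between cyclopamine libraries and 0.0899 between DMSO libraries. On the first 2 principal components, which held 46.3% and 18.1% of the variance, DMSO libraries lay together, and estradiol replicate 3 lay at 57.4 on the second, against 11.4 and 3.5 for the other estradiol libraries.

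The comparison of cyclopamine with DMSO asked which transcripts change in brains exposed to this Smoothened blocker. With this compound alone, a change cannot be assigned to Smoothened. Most Hedgehog target genes fell, and gli1 and hhip most. The transcriptional effector gli1 fell from 14.5 ± 0.689 CPM in DMSO to 0.214 ± 0.0718 CPM (log2 fold change -6.06 ± 0.32, n = 3 per group, adjusted p = 1.85e-05). The ligand-binding antagonist hhip (-4.33 ± 0.34) and the receptor ptch1 (-1.49 ± 0.12) fell as well. In all, 5 of 6 measured targets fell, also when adjusted over the list alone (5), and none rose; the list test gave an adjusted p of 8.18e-07, and an adjusted p = 0.15 with an estimated correlation. Among pathway components, scube2 and cdon, which help to release and bind the ligand, rose by 0.93 ± 0.22 and 0.68 ± 0.16 (calls lost without DMSO replicates 1 or 2, and for cdon also 3), while the ligand shh (0.39 ± 0.18, adjusted p = 0.147) and smo (-0.34 ± 0.20, adjusted p = 0.234) did not pass.

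**Figure D1:**
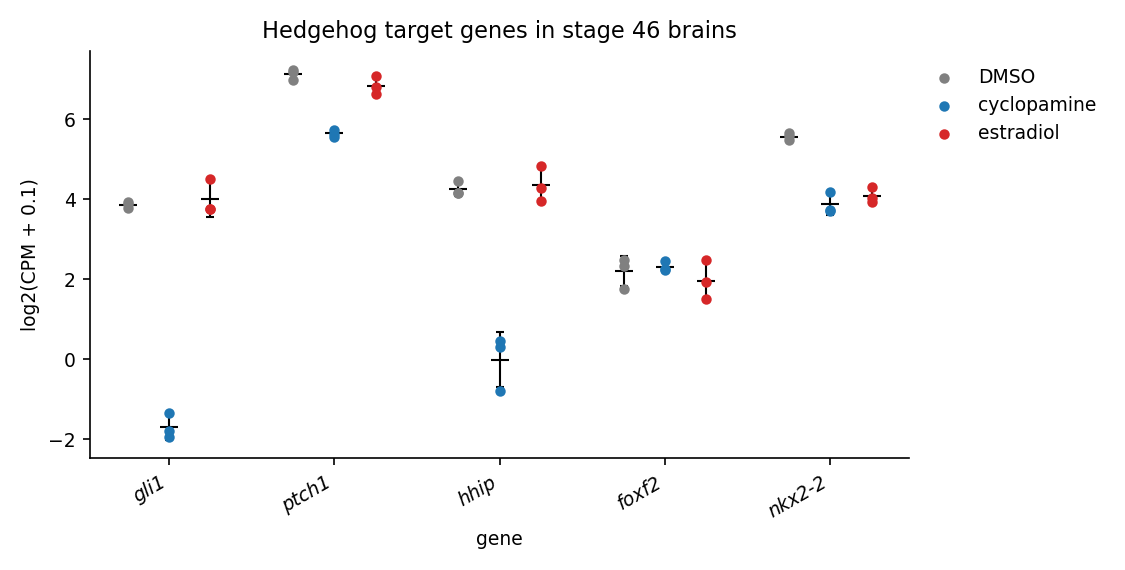
Levels of 5 of the 6 measured Hedgehog targets, as log2(CPM + 0.1), in each DMSO, cyclopamine and estradiol library; points are libraries and bars are the mean ± SD of 3. In cyclopamine gli1 averaged 0.214 CPM, against 14.5 CPM in DMSO and 16.5 CPM in estradiol.

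Transcription factors of ventral and anterior brain regions were lower with cyclopamine. Of 12 ventral identity genes 7 fell (7 fell and 1 rose when adjusted over the list alone), among them nkx2-1, a marker of the hypothalamus and ventral forebrain (-1.93 ± 0.24), nkx2-2 (-1.69 ± 0.15) and olig2 (-1.10 ± 0.13); the adjusted p was 0.00539, and the adjusted p = 0.348 with an estimated correlation. Of 16 telencephalic genes 12 fell (13 adjusted over the list alone), including dlx1 (-1.46 ± 0.21), with an adjusted p of 1.02e-06 and an adjusted p = 0.317 with an estimated correlation. Of 26 genes of neurogenesis and newborn neurons 16 fell (17 fell and 1 rose adjusted over the list alone), led by the proneural factors neurog1 (-1.91 ± 0.22) and neurog2 (-1.60 ± 0.21); the adjusted p was 4.74e-07, and the adjusted p = 0.15 with an estimated correlation. Of 26 neural progenitor genes 11 fell (13 fell and 2 rose adjusted over the list alone), such as sox1 (-1.07 ± 0.15), with an adjusted p of 0.000787 and an adjusted p = 0.682 with an estimated correlation. The cell cycle list had 15 of 30 members lower (25 adjusted over the list alone), including mcm5 (-1.64 ± 0.29) and mki67 (-0.85 ± 0.20, a call lost without cyclopamine replicates 1 or 3 and without each DMSO replicate); its adjusted p was 1.59e-07, and the adjusted p = 0.594 with an estimated correlation. Of 32 genes of mature neurons and synapses 4 fell (2 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.144, median -0.17).

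Several groups rose with cyclopamine. Cholesterol biosynthesis had 17 of 21 genes higher (18 adjusted over the list alone), including fdft1 (1.05 ± 0.13), with an adjusted p of 1.2e-12 and an adjusted p = 0.267 with an estimated correlation. Leukocyte and microglia genes rose in 10 of 11 cases (10 adjusted over the list alone), for example the protease ctss (1.89 ± 0.14) and the myeloid factor spi1 (1.49 ± 0.26), with an adjusted p of 1.06e-08 and an adjusted p = 0.15 with an estimated correlation. Endothelial genes rose in 10 of 15 cases (11 adjusted over the list alone), for example pecam1 (2.55 ± 0.34) and cldn5 (0.99 ± 0.19), with an adjusted p of 4.28e-07 and an adjusted p = 0.348 with an estimated correlation.

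Transcripts of tissues outside the brain were also higher in cyclopamine libraries. Skeletal muscle genes rose in 10 of 13 cases (11 adjusted over the list alone), led by mylpf (4.24 ± 0.44), with an adjusted p of 1.57e-11 and an adjusted p = 0.15 with an estimated correlation. Melanocyte genes rose in 6 of 9 cases (6 adjusted over the list alone), led by tyr (2.90 ± 0.48), with an adjusted p of 2.67e-05 and an adjusted p = 0.348 with an estimated correlation. The mean of the epidermis list was 2.60 log2 CPM in cyclopamine replicate 1, 4.81 in replicate 2 and higher still in replicate 3, against 2.30 ± 0.30 in DMSO; 2 of 11 epidermal genes rose (9 adjusted over the list alone), with an adjusted p of 0.00101 and an adjusted p = 0.348 with an estimated correlation. Several of the largest rises had a wide spread between those libraries, such as elf3, an epithelial transcription factor (23 ± 23.5 CPM against 0.107 ± 0.0935 CPM in DMSO); its call was lost without cyclopamine replicates 2 or 3 and without each DMSO replicate. Retina and lens genes went the other way, with 3 of 13 lower (6 adjusted over the list alone), an adjusted p of 0.000357 and an adjusted p = 0.348 with an estimated correlation; the list mean was 0.65 ± 1.30 log2 CPM with cyclopamine (2.14 in replicate 3) and 2.56 ± 0.15 in DMSO.

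In total 3171 of 16212 genes changed with cyclopamine, 1616 up and 1555 down, and with relative log expression size factors the split was 1763 up and 862 down. The count was 1787 without cyclopamine replicate 1, 1423 without cyclopamine replicate 3, and 1127, 1337 and 1767 without DMSO replicates 1, 2 and 3. With cyclopamine replicate 1, the cyclopamine library with the lowest mean of epidermal genes, alone in its group, 1170 genes changed (1025 up, 145 down), and with a filter at 5 CPM 1934 did, both settings chosen after the data were seen. Of 126 calls of named genes, 117 held with relative log expression size factors, and 80 to 107 held without a single library.

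The comparison of estradiol with DMSO asked what an estrogen changes in the same tissue. Ventral and telencephalic genes were lower here too. The hypothalamic and ventral forebrain factor nkx2-1 fell by 1.90 ± 0.24 on the log2 scale (9.79 ± 3.82 CPM against 36.4 ± 1.82 CPM in DMSO, adjusted p = 0.00735), nkx2-2 fell by 1.48 ± 0.15, and vax2, a factor of the ventral eye and forebrain, fell by 2.39 ± 0.22. Of 12 ventral identity genes 4 fell (7 fell and 2 rose adjusted over the list alone), with an adjusted p of 0.00294 and an adjusted p = 0.377 with an estimated correlation. Of 16 telencephalic genes 7 fell (10 adjusted over the list alone), among them tbr1, eomes, dlx1 and dlx2, with an adjusted p of 7.62e-11 and an adjusted p = 0.208 with an estimated correlation. Genes of GABA and glycine signalling fell in 4 of 18 cases (8 adjusted over the list alone). The 4 were the interneuron factors dlx1, dlx2, dlx5 and lhx6, of which dlx1 and dlx2 are also in the telencephalic list. The adjusted p was 5.77e-08, and the adjusted p = 0.378 with an estimated correlation. This list was lower with both drugs: its mean was 5.46 ± 0.47 log2 CPM with estradiol and 5.52 ± 0.12 with cyclopamine, against 6.2 ± 0.086 in DMSO.

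Of the Hedgehog targets, gli1 did not pass with estradiol: it stood at 16.5 ± 5.49 CPM (log2 fold change 0.19 ± 0.21, adjusted p = 0.63), and hhip and ptch1 had adjusted p of 0.803 and 0.196. The list of 6 had an adjusted p of 0.0756 and 1 lower member (1 adjusted over the list alone), nkx2-2, which is also in the ventral identity list. Over its alternatives that p ran from 0.000837, without estradiol replicate 3, to 0.508, with an estimated correlation. Of 11 estrogen response genes 2 fell (3 adjusted over the list alone) and none rose; both were prolactin genes (prl.1, prl.2), which are also pituitary genes. The estrogen receptor genes esr1 and esr2 were in neither table, and aromatase, cyp19a1, did not pass (adjusted p = 0.154). The vitellogenin gene vtga2 stood at 1.75 ± 0.512 CPM with estradiol and 1.21 ± 0.42 CPM in DMSO (adjusted p = 0.383).

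Leukocyte genes rose with estradiol in 6 of 11 cases (9 adjusted over the list alone), such as ctss (0.97 ± 0.14) and mpo, a granulocyte enzyme (1.94 ± 0.33), with an adjusted p of 8.44e-08 and an adjusted p = 0.208 with an estimated correlation. The complement gene c3 rose from 41.9 ± 9.47 to 475 ± 99.7 CPM, an 11.3-fold difference, a call lost without estradiol replicates 1 or 3 and without each DMSO replicate. The cell cycle list had 1 of 30 members higher over all genes tested, tyms (1.47 ± 0.31, lost without the same libraries), and 28 when adjusted over the list alone, with a median of 1, an adjusted p of 4.5e-12 and an adjusted p = 0.421 with an estimated correlation. Its mean was 4.26, 4.06 and 5.32 log2 CPM in estradiol replicates 1, 2 and 3. Of 19 immediate early genes 4 fell (9 adjusted over the list alone): fosb, egr4, egr3 and nr4a1, with an adjusted p of 1.83e-05 and an adjusted p = 0.377 with an estimated correlation. Transcripts of other tissues were higher as well, with 2 of 13 muscle genes (7 adjusted over the list alone), 2 of 9 melanocyte genes (3 adjusted over the list alone) and 1 of 8 red blood cell genes (5 adjusted over the list alone), slc4a1, past the threshold. The adjusted p were 1.8e-06, 0.0222 and 9.92e-05, and the adjusted p = 0.319, 0.526 and 0.424 with an estimated correlation. The melanocyte list did not pass without estradiol replicates 2 (0.126) or 3 (0.0829) or DMSO replicate 3 (0.0508).

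In total 335 genes changed with estradiol, 200 up and 135 down, and 3622 had an unadjusted p under 0.05. The count was 200 without estradiol replicate 1, 1510 without estradiol replicate 2, and 27, 59 and 56 without DMSO replicates 1, 2 and 3. DESeq2 called 1451 genes, and limma on the deposited quantile-normalized values called 197, with 86 up and 111 down. Of 49 calls of named genes, 31, 49 and 35 held without estradiol replicates 1, 2 and 3, and 9, 20 and 13 without DMSO replicates 1, 2 and 3. Those of nkx2-1, nkx2-2, vax2, tbr1, gh1, prl.1 and pou1f1 held without each of these libraries.

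Most pituitary genes were lower with both drugs. Growth hormone, gh1, stood at 54.1 ± 5.67 CPM in DMSO and 2.87 ± 1.43 CPM with cyclopamine, and had 0 counts in the 3 estradiol libraries, at least 1250-fold lower. The pituitary factor pou1f1 fell from 2.8 ± 0.909 CPM to 0.185 ± 0.0299 CPM with estradiol and 0.156 ± 0.0843 CPM with cyclopamine. The hormone precursor pomc fell by 2.60 ± 0.45 with estradiol and by 1.90 ± 0.44 with cyclopamine; both calls were lost without replicate 3 of the drug and without each DMSO replicate, and the second also without cyclopamine replicate 2. Of 11 measured pituitary genes 6 fell with estradiol (9 fell and 1 rose adjusted over the list alone) and 9 with cyclopamine (9 adjusted over the list alone). The adjusted p were 1.05e-09 and 1.02e-06, and the adjusted p = 0.148 and adjusted p = 0.15 with an estimated correlation.

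**Figure D2:**
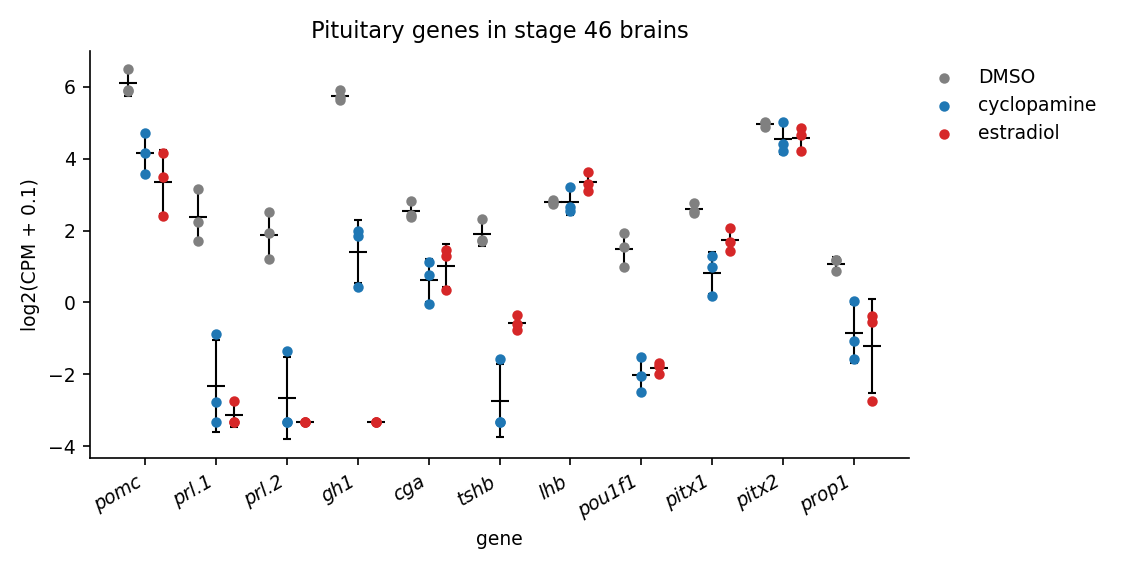
Levels of the 11 measured pituitary genes, as log2(CPM + 0.1), in each DMSO, cyclopamine and estradiol library; points are libraries and bars are the mean ± SD of 3. In DMSO gh1 averaged 54.1 CPM, in cyclopamine 2.87 CPM and in estradiol 0.

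Of the genes called for both drugs, 170 were higher in both and 113 lower in both, 283 in all, against 19.9 and 12.9 for independent lists. Unchanged groups, with DMSO libraries that were simulated too, were drawn 20 times around the real DMSO means. They had between 0 and 3 calls per contrast, too few to show how many shared calls the shared controls bring. Fold changes of the drugs correlated across genes (Pearson's r = 0.769), where the simulated groups gave an r of 0.515 ± 0.015 (SD); genes are not independent replicates. The covariance was 0.401 against a simulated 0.0503, a difference of 0.351, and 72.8% of genes had the same sign with both drugs against a simulated 66.7%. The simulation gave all libraries the same spread per gene. The real DMSO libraries varied less than the drug libraries (biological coefficient of variation 0.0899, against 0.227 with estradiol and 0.21 with cyclopamine). The simulated values therefore do not measure what these controls bring. How much of the correlation comes from the shared controls stays open, since they could not be split. The shared count was 168 without estradiol replicate 1, 911 without estradiol replicate 2, 179 without cyclopamine replicate 3, and 25, 55 and 52 without DMSO replicates 1, 2 and 3. DESeq2 gave 1000 shared genes and the deposited quantile-normalized values 164.

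Set directly against each other, the drugs differed in Hedgehog targets, the cell cycle, cholesterol synthesis and muscle genes, among other lists. Of 6 Hedgehog targets 4 were higher with estradiol than with cyclopamine (4 adjusted over the list alone), led by gli1 (6.25 ± 0.32) and hhip (4.46 ± 0.34), with an adjusted p of 7.4e-07 and an adjusted p = 0.28 with an estimated correlation. Cell cycle genes were higher with estradiol in 28 of 30 cases (29 adjusted over the list alone), for example mcm5 (2.52 ± 0.29) and rrm2.2 (2.51 ± 0.29), with an adjusted p of 2.68e-27 and an adjusted p = 0.281 with an estimated correlation. Cholesterol synthesis genes were lower with estradiol in 10 of 21 cases (18 adjusted over the list alone), and muscle genes in 8 of 13 (10 adjusted over the list alone). These lists had adjusted p of 1.37e-14 and 9.61e-10, and the adjusted p = 0.28 for each with an estimated correlation. Growth hormone was at least 67.2-fold lower with estradiol than with cyclopamine. The telencephalic and ventral lists did not pass between the drugs (adjusted p = 0.501 and 0.358).

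Between the drugs 1097 genes differed, 675 higher with estradiol and 422 higher with cyclopamine, and with relative log expression size factors the split was 473 and 516. The count was 535, 712 and 444 without cyclopamine replicates 1, 2 and 3, 289 in a fit of only these libraries, 1782 with DESeq2, and 329 with cyclopamine replicate 1 alone in its group, a setting chosen after the data were seen. Of 55 calls of named genes, 30 held in the fit of only these libraries, 42, 46 and 36 without cyclopamine replicates 1, 2 and 3, and 25 with cyclopamine replicate 1 alone.

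**Figure D3:**
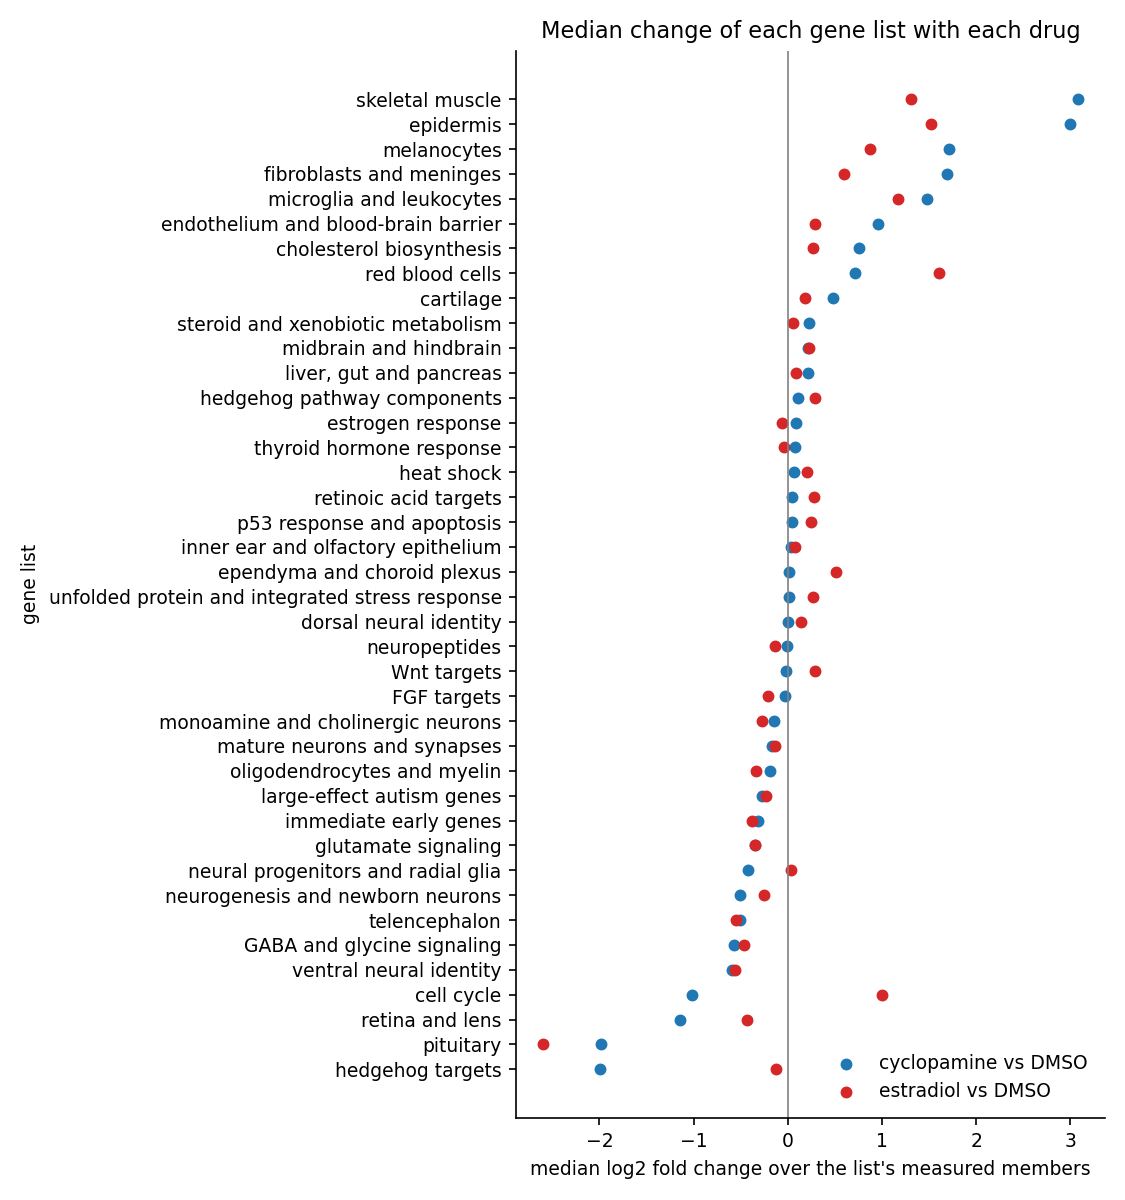
Median log2 fold change of each fixed gene list with estradiol (red) and cyclopamine (blue) against DMSO, over the list's measured members; lists are sorted by the cyclopamine value. The cell cycle list lay at 1 with estradiol and -1.02 with cyclopamine, and the pituitary list at -2.60 and -1.98.

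Among 10 large-effect autism risk genes, reported whatever their values, edgeR called 0 with estradiol (0 adjusted over the list alone), as did DESeq2 and limma; 2 had an unadjusted p under 0.05, arid1b (-0.28 ± 0.10) and adnp (-0.19 ± 0.08). Without estradiol replicate 2, arid1b and ank2 (-0.33 in the fit of all libraries) were called. The list as a whole had an adjusted p of 0.0133 and a median of -0.23, and an adjusted p = 0.377 with an estimated correlation. With cyclopamine 3 fell (4 adjusted over the list alone): chd8 (-0.40 ± 0.08), arid1b (-0.34 ± 0.10) and adnp (-0.29 ± 0.08), with an adjusted p of 0.0291 for the list and an adjusted p = 0.366 with an estimated correlation. The list did not pass without cyclopamine replicate 3 (0.0558) or DMSO replicates 1 (0.0695) or 2 (0.0534). The calls of arid1b and adnp were lost with relative log expression size factors and without most single libraries, and that of chd8 without cyclopamine replicate 3.

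The untreated time course asked how brain expression changes from stage 40 to stage 47. Cell cycle and progenitor genes fell, and synaptic genes rose. The cell cycle list had 29 of 30 members lower at stage 47 than at stage 40 (29 adjusted over the list alone), with a median log2 fold change of -4.01; ccnb1.2, a mitotic cyclin, fell from 96.5 to 2.76 CPM (-5.13 ± 0.10, adjusted p = 5.24e-21). Its adjusted p was 1.97e-15, and the adjusted p = 0.284 with an estimated correlation. Of 27 neural progenitor genes 26 fell and 1 rose (26 and 1 adjusted over the list alone), with nes lower by 6.31-fold and vim by 3.6-fold, an adjusted p of 9.57e-06 and an adjusted p = 0.403 with an estimated correlation. Of 26 genes of neurogenesis 20 fell and 4 rose (20 and 4 adjusted over the list alone), with an adjusted p of 0.000215 and an adjusted p = 0.403 with an estimated correlation. Genes of mature neurons and synapses rose in 29 of 32 cases and fell in 2 (29 and 2 adjusted over the list alone), such as the neurofilament nefl (3.66 ± 0.11) and stx1a (1.86 ± 0.07), with an adjusted p of 2.45e-07 and an adjusted p = 0.284 with an estimated correlation. Neuropeptide genes rose in 21 of 23 cases (21 adjusted over the list alone), such as vip (2.91 ± 0.12), with an adjusted p of 2.78e-06 and an adjusted p = 0.266 with an estimated correlation. Glutamate signalling genes rose in 16 of 17 cases (16 adjusted over the list alone), with an adjusted p of 0.000115 and an adjusted p = 0.403 with an estimated correlation.

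**Figure D4:**
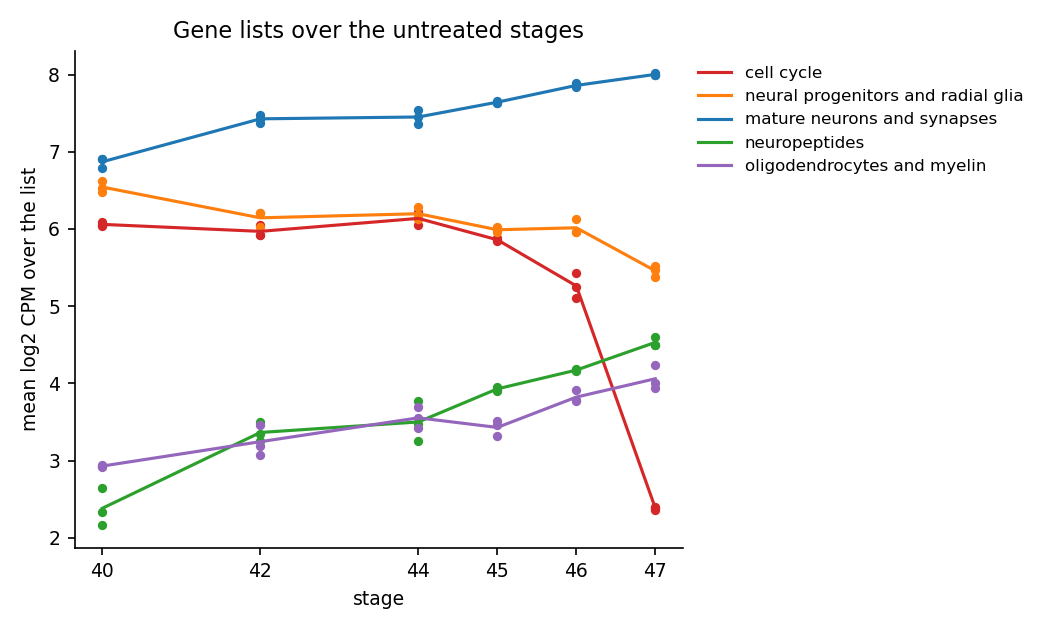
Mean log2 CPM of 5 gene lists at each untreated stage; points are libraries and lines join the means of 3. The cell cycle list went from 6.06 at stage 40 to 5.26 at stage 46 and 2.38 at stage 47, and the synapse list from 6.87 to 8.

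Myelin genes rose in 8 of 14 cases and fell in 3 (8 and 3 adjusted over the list alone), with mag higher by 10.5-fold; the list as a whole did not pass (adjusted p = 0.17). Of 11 pituitary genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list did not pass (adjusted p = 0.633); gh1 was higher at stage 47 by 7.43 ± 0.97 and prl.1 by 7.66 ± 0.85 on the log2 scale. The amino acid transporter slc7a2.2 had 0 counts at stage 40 and was at least 202-fold higher at stage 47, and the tyrosine aminotransferase gene tat rose by 9.80 ± 0.24. Transcripts of other cells went different ways: red blood cell genes fell in 8 of 11 cases (8 adjusted over the list alone), with hbe1 lower by 49.7-fold, and melanocyte genes fell in 8 of 10 and rose in 1 (8 and 1 adjusted over the list alone). Their adjusted p were 0.0323 (0.0513 without stage 40 replicate 3) and 0.0278, and the adjusted p = 0.535 and adjusted p = 0.403 with an estimated correlation. Leukocyte genes rose in 7 of 10 cases (7 adjusted over the list alone), endothelial genes rose in 5 of 15 and fell in 3 (5 and 3 adjusted over the list alone), and fibroblast genes rose in 5 of 11 and fell in 5 (5 and 5 adjusted over the list alone); these lists did not pass (adjusted p = 0.123, 0.728 and 0.859). Of the autism risk genes, scn2a was among 4 that rose, by 2.28 ± 0.11, and chd8 was among 3 that fell, by 0.90 ± 0.08 (4 and 3 adjusted over the list alone).

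Over all stages 14180 of 16049 genes changed, and 12973 differed between stages 47 and 40, 6420 up and 6553 down. Adjacent stages differed in 7549 genes (42 against 40), 373 (44 against 42), 3667 (45 against 44), 6760 (46 against 45) and 7835 (47 against 46). In the last step ccnb1.2 was lower by 18-fold and bhmt, an enzyme of methionine metabolism, was higher by 18.8-fold. From stage 42 to 44, tat was higher by 7.28-fold, and this count was 1176, 143 and 173 without stage 42 replicates 1, 2 and 3, 170 and 247 without stage 44 replicates 1 and 3, 120 in a fit of only these libraries and 597 with DESeq2. Stage 44 replicate 3 stood apart in pituitary genes, with 0 counts of pou1f1 and 1.7 CPM of pomc, against 36.4 and 86.1 CPM of pomc in the other stage 44 libraries.

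Genes that rise or fall over these stages were then followed in the drug libraries. The 200 stage-falling genes, 24 of them cell cycle list members, had a median log2 fold change of 0.60 with estradiol (5 rose) and -0.58 with cyclopamine (92 fell), and 140 of them were higher with estradiol than with cyclopamine. Adjusted p were 1.71e-15, 1.1e-18 and 6.07e-60, and the adjusted p = 0.429, 0.429 and 0.341 with an estimated correlation. The 200 stage-rising genes had medians of -0.16 and -0.03. Their adjusted p was 3.76e-06 with estradiol, 0.601 without estradiol replicate 3, and the adjusted p = 0.429 with an estimated correlation. With cyclopamine it was 0.221, in a test that pointed up while the median was negative, and 22 genes rose and 7 fell. On the deposited quantile-normalized values the list passed as higher with cyclopamine. Between the drugs the median was -0.12, lower with estradiol, with an adjusted p of 2.79e-09 and an adjusted p = 0.429 with an estimated correlation.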

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

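The tests of explanations and the counts of other splits were chosen only after the results had been seen; the direct test between the drugs was planned.

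Results were singled out where both drugs passed against DMSO in opposite directions, for lists at the preset correlation, and the direct test between them passed. For a gene the direct difference is the gap between its 2 changes against DMSO. After picking opposite changes, the direct test is therefore no separate check. The cell cycle list was higher with estradiol than with cyclopamine by a median of 1.99 on the log2 scale (adjusted p = 2.68e-27, and adjusted p = 0.281 with an estimated correlation), and the stage-falling list by 0.95 (adjusted p = 6.07e-60, and adjusted p = 0.341 with an estimated correlation). The same held for 6 genes, by 2.16 for atad2, 2.54 for esco2, 2.15 for e2f8, 2.45 for chaf1b, 2.56 for tyms and 2.2 for the gene with the provisional name rabepk; these were named because of this count, and tyms also by the rule. With estradiol these 6 passed narrowly against DMSO (adjusted p from 0.0373 to 0.0486), where calls went from 335 to 27, 59 and 56 without DMSO replicates 1, 2 and 3, and tyms was lost without each of them and without estradiol replicates 1 or 3.

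The mean of the cell cycle list was higher with estradiol and lower with cyclopamine than in DMSO, with 1 of 30 members past the threshold with estradiol and 15 with cyclopamine, and adjusted p = 0.421 and adjusted p = 0.594 with an estimated correlation. Without estradiol replicate 3 the list mean still lay 1.44 ± 0.106 (SE) above cyclopamine, which argues against that library alone making this difference. The list mean then lay 0.484 ± 0.147 above DMSO (0.872 ± 0.406 with that library). This rests on estradiol replicates 1 and 2 only, too few to settle how much of the difference from DMSO replicate 3 makes. In untreated brains the list mean fell by 2.88 from stage 46 to stage 47, while that of the stage-rising genes went up by 0.634. Faster development with cyclopamine would by that ratio have raised the stage-rising genes by 0.211 ± 0.0257, and they lay at 0.018 ± 0.036. Other values went with faster development. Fold changes with cyclopamine correlated with those of untreated development over 15608 genes (Pearson's r = 0.18). Of the 200 stage-falling genes, 24 of them in the cell cycle list, 92 fell and 0 rose. Of the stage-rising genes 22 rose and 7 fell. The list means, in log2 CPM, went both ways. The GABA and glycine list rose from 5.2 at stage 40 to 6.1 at stage 47. With cyclopamine it was lower, at 5.52 ± 0.12 against 6.2 ± 0.086 in DMSO. Cholesterol synthesis fell from 5.3 to 4.62 over the stages, but was 5.54 ± 0.15 with cyclopamine against 4.71 ± 0.09. Neural progenitor genes fell from 6.54 to 5.46, and were 5.69 ± 0.17 with cyclopamine against 6.18 ± 0.11. Faster development with cyclopamine therefore stays open, as values go both ways and the ratio rests on the last step alone. For slower development with estradiol the matching shift was -0.192 ± 0.0895 and the measured one -0.167 ± 0.13, so a delay and an effect of the drug on proliferation cannot be told apart with 3 libraries. A direct effect of either drug on proliferation stays open and untested.

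Pituitary genes were lower in 6 of 11 cases with estradiol and 9 with cyclopamine, with adjusted p = 0.148 and adjusted p = 0.15 for the list with an estimated correlation. Slower development, to stage 40 or later, would lower the mean of the 11 pituitary genes by no more than the change from stage 46 to stage 40, the lowest stage (-1.44 ± 0.122), but it changed by -2.73 ± 0.274 with cyclopamine and -3.02 ± 0.219 with estradiol, each within its own table, which is -1.29 ± 0.3 and -1.58 ± 0.251 beyond it. With each drug 2 of the 11 fell less than that (gh1 and prl.1 with cyclopamine, tshb and cga with estradiol), and 2 earlier tests had compared levels between the tables: pou1f1 and prl.2 alone decided nothing (2 of 4 drug means more than 1 SD below the lowest stage), and the mean of all 11 lay -1.27 ± 0.272 and -1.56 ± 0.216 from it. A pituitary lost in dissection predicts equal losses of gh1 and pomc, and with cyclopamine the loss of pomc was 2.33 ± 0.558 log2 units smaller. This SE treats gh1 and pomc as independent, although both were measured in the same libraries. The smaller loss of pomc does not settle the question, because pomc is also made outside the gland. Only 1 untreated library, stage 44 replicate 3, had 0 counts of pou1f1 to show the level of pomc there. That library held 1.7 CPM of pomc, against 5.22 to 26.4 CPM in the estradiol and cyclopamine libraries, which were normalized separately from it. Loss in dissection and a drug effect on the gland therefore cannot be told apart.

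Leukocyte genes were higher in 6 of 11 cases with estradiol and 10 with cyclopamine, with adjusted p = 0.208 and adjusted p = 0.15 for the list with an estimated correlation. A lower share of brain tissue would raise other cell types alike. Yet 5 of 11 other cell type lists lay more than 2 SE below the leukocyte list in both drugs. These were cartilage, endothelium, inner ear and olfactory epithelium, and pituitary and retina and lens, whose means were below DMSO with both drugs. Others were not lower: muscle genes rose by 1.15 with estradiol and 2.6 with cyclopamine, and epidermal genes by 1.13 and 2.07. Leukocyte genes rose by 1.02 and 1.39. The values argue against a rise of all tissues alike, and leave open that some tissues were carried along. Epidermis carried along would leave leukocyte genes low where epidermal genes are low. In estradiol replicate 3 and cyclopamine replicate 1 epidermal genes lay within the DMSO range. There the leukocyte list stood at 2.66 and 3.04 log2 CPM, against at most 1.56 in DMSO, which argues against epidermis alone. Low epidermal genes do not mark a library free of other tissue: muscle genes averaged 2.84 ± 0.28 log2 CPM with cyclopamine, against 0.24 ± 0.18 in DMSO. More blood stays open: edgeR called 0 of 8 red blood cell genes with cyclopamine (0 adjusted over the list alone) and 1 with estradiol, and the globin gene hba3, called with neither drug (adjusted p = 0.128 and 0.1), stood at 517 ± 180 CPM with cyclopamine and 833 ± 548 CPM with estradiol, against 222 ± 77.7 CPM in DMSO. The leukocyte list exceeded the red blood cell list by 0.555 ± 0.279 with cyclopamine and by -0.331 ± 0.491 with estradiol, and neither difference reached 2 SE, so blood and leukocytes in the tissue cannot be told apart.

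For comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split gave the most genes (1 of 10 splits as large) in each: 335 with estradiol (highest other 0), 3171 with cyclopamine (0), 1097 between the drugs (1), 12973 for stage 47 against 40 (0), 7549 for 42 against 40 (0), 373 for 44 against 42 (191), 3667 for 45 against 44 (0), 6760 for 46 against 45 (0) and 7835 for 47 against 46 (0). For the 14180 genes that differed among stages the real split gave the most (1 of 50 drawn, highest other 6708), a share under 0.05. The same held for the 283 genes shared by both drugs (1 of 100 splits drawn, highest other 201). That cannot tell a shared effect from the shared reference, since the splits mix real groups. The split with 201 had the cyclopamine libraries as the common reference. A split that kept the DMSO libraries and mixed the drugs gave 95. For list calls at the preset correlation the real split gave the most with estradiol (25, 1 of 10 as large, highest other 20) and with cyclopamine (20, 1 of 10, highest other 18), where the splits are again too few. Other splits gave at least as many list calls between the drugs (17, 5 of 10 as large, highest other 23) and for stage 47 against 40 (15, 2 of 10, highest other 18).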

How the results depend on the processing

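The filters at 5 CPM and the fits with cyclopamine replicate 1 alone were chosen after the data were seen. The planned filters (none, and 1 CPM in at least 3 libraries) removed no gene and so tested nothing. No named gene reversed in any alternative run. Depth limited what could be seen near the floor of 0.105 to 0.17 CPM in the drug libraries. Where a count moved by over 1.5 times the cause was not tested, beyond fewer libraries in the fit. Leaving out each library in turn, counts ranged from 27 to 1510 for estradiol (335), from 1127 for cyclopamine (3171), from 444 between the drugs (1097), from 143 to 1176 for stage 44 against 42 (373), and from 25 to 911 for both drugs (283). DESeq2 gave 1451 with estradiol, 1782 between the drugs, 597 for stage 44 against 42 and 1000 for both drugs. The deposited quantile-normalized values gave 197 with estradiol and 164 for both drugs. Fits of only the groups compared gave 289 between the drugs and 120 for stage 44 against 42. The 5 CPM filter gave 1934 with cyclopamine; replicate 1 alone gave 1170 with cyclopamine and 329 between the drugs. Without cyclopamine replicate 2 the cyclopamine count was 2633, and without estradiol replicate 2 the count between the drugs was 1482. Other counts stayed within 1.5 times.

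With an estimated correlation the Hedgehog list in cyclopamine went from an adjusted p of 8.18e-07 to 0.15, while fry gave 0.000143. Other list calls in the drug contrasts then went from 61 to 0 (29 with fry). Those of stage 47 against 40 went from 15 to 0 (34 with fry). Stage-rising calls went from 2 to 0 (0 with fry) and stage-falling calls from 3 to 0 (1 with fry). Without estradiol replicate 3 the Hedgehog list in estradiol passed (0.000837; 0.298 without replicate 1), 1 stage-rising call was left, and the neuropeptide list turned to higher without passing (0.689; lower at 0.000132 without replicate 1).

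The replicate numbers did not pair the samples: 2 of 9 same-number pairs in the drug table and 2 of 45 in the time course correlated over 0.1, and 1 of 9 and 5 of 18 libraries correlated best with their own number. With the replicate block the counts were 413, 2910 and 859 in the drug contrasts, 333 for both drugs, 12942, 7518, 342, 3600, 6681 and 7779 in the stage contrasts and 14105 over all stages.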

Other observations

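With cyclopamine, lysosomal genes rose as well: of 36 genes that are not leukocyte markers 29 rose, with a median log2 fold change of 1.02 (camera p = 2.55e-27, and p = 0.0224 with an estimated correlation). With estradiol 1 of them rose, with a median of 0.26 (p = 9.85e-09, and p = 0.157 with an estimated correlation). This list was put together after the data had been seen. Some drug handling genes also rose with cyclopamine: cyp3a4.3, a drug-metabolizing cytochrome, was higher by 4.9-fold, abcg2, an efflux pump, by 1.73-fold, and nqo1 by 2.72-fold. The latter 2 calls were lost without DMSO replicates 1 or 2, and that of abcg2 also without cyclopamine replicate 1. Of the 11 measured genes of the steroid and xenobiotic metabolism list, 4 rose (5 adjusted over the list alone), with an adjusted p of 0.00714 and an adjusted p = 0.348 with an estimated correlation. The cytochrome cyp3a4.3 also rose with estradiol, by 1.91-fold, a call lost without estradiol replicate 1 and without each DMSO replicate.

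In the time course, 8 of 12 heat shock genes were lower and 1 higher at stage 47 than at stage 40 (8 and 1 adjusted over the list alone), with hsph1 lower by 10.8-fold; the list did not pass (adjusted p = 0.0505, and adjusted p = 0.403 with an estimated correlation). Of 17 genes of the unfolded protein response 9 fell and 3 rose (9 and 3 adjusted over the list alone), with hspa5 lower by 4.69-fold and manf by 7.77-fold, an adjusted p of 0.0337 and an adjusted p = 0.403 with an estimated correlation. Of 6 thyroid hormone response genes 3 rose, thrb by 10-fold, and 2 fell (3 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.633).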
